A study of Mus musculus with 3 samples.

How the data were processed

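RNA was measured in ScxGFP-positive cells from embryonic mouse hindlimbs at 3 stages, E11.5, E13.5 and E15.5, in 1 library per stage. Per the labels' protocols, GFP-positive cells were sorted on a BD FACSAria II instrument and frozen, total RNA was extracted with an RNeasy micro kit, and cDNA was made with the NuGEN Ovation RNA-Seq v2 assay, which amplifies small amounts of RNA. Mice were of mixed strain background. Each library came from a pool of 18, 12 or 11 hindlimbs in stage order, so differences between embryos are averaged within a pool and were not measured. Samples were grouped by the age given in the labels.

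The deposited values are FPKM, fragments per kilobase of transcript scaled to the number of mapped fragments, 1 value for each RefSeq transcript in each library, made by the authors. The deposited tables also hold a coverage column, a signal equal to the mean read depth over the transcript, and per the file headers a status for each estimate (OK, LOWDATA, FAIL or HIDATA). Bowtie 0.12.7, TopHat 1.4.1 and the mouse build mm9 are named in the submitters' processing notes, with no role or order. The strand setting, the annotation release and filters are not given in the sources used here. The kit and the estimation can affect the values in several ways. Amplified cDNA from few cells adds noise that counting intervals do not cover, reads are divided among transcripts by an estimate, and genes with near-identical copies can share reads. No strand is stated, so overlapping genes cannot be told apart by strand. The tables hold 0 rows of the mitochondrial genome.

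Coverage divided by FPKM was a single constant within each library (1.61, 1.32 and 1.58 in stage order), so coverage was used only to estimate depth. Values were not whole multiples of 1 read. Covered bases were counted in bins inside a preset window of low values, among transcripts of single-transcript genes longer than 1000 bases. The tallest bin after smoothing, 41 bases, was taken as 1 read, and the window limits what this value could be. This gave about 14400000, 12800000 and 17900000 reads on the listed transcripts, which are not whole-library totals. The Poisson intervals of single genes rest on this estimate, are approximate and cover counting error only. At 10 FPKM a transcript of 2000 bases had a counting error of 3.57%, 3.94% and 3.60%.

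FPKM values of transcripts that share a gene symbol were summed, which gave 22072 genes, 3793 of them with several transcripts. The plan, written before the data were examined, took each row as 1 gene. Since the tables hold 1 row per transcript, the sum per symbol was made the main value, and the rows as deposited are given as an alternative. Changes were computed on the log2(FPKM + 1) scale, where the pseudocount of 1 understates changes of low genes. Genes entered a comparison with a mean FPKM of at least 1 over the 3 libraries and a status of OK for every transcript in both libraries, and were counted as higher or lower at 2-fold or more on that scale. In all, 11027 genes passed the filter on the mean, and 88 of these were left out of the comparison of E15.5 with E11.5 for their status. No test between stages was made, since each stage has 1 library. As a description of counting noise alone, 100 simulated pairs of libraries with no change gave 5.8 calls on average and 12 at most.

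Gene lists fixed before the data were examined, 34 with 608 entries, were each summarised by the median log2 change of members with a mean FPKM of at least 1. They cover tendon regulators, tendon matrix, collagens and their processing, elastic fibres, matrix proteases, cartilage, bone, joint, limb patterning, Hox genes, muscle, blood, endothelium, leukocytes, epidermis, Schwann cells, neurons, smooth muscle, fibroblasts, cell cycle and its inhibitors, signalling pathways (TGF-beta and BMP, FGF, Wnt, retinoic acid), integrins, glycolysis, immediate-early genes, ribosomal proteins, housekeeping, sex-linked and imprinted genes. Some genes stand on several lists. Each median was set against 10000 random lists of the same size matched on mean expression in 20 bins, and called apart where it lay in the outer 2.5% at either end. Intervals of medians come from 10000 bootstrap draws of members. Both describe these libraries only. With at least 3 measured members needed, 93 list medians were compared in the 3 comparisons. About 1 in 20 would be called apart if members were drawn at random and independently. Genes of a list can change together and the comparisons share libraries, so the chance rate for such lists is not known. Called above random lists were 19 medians for E11.5 to E13.5, 15 for E13.5 to E15.5 and 22 for E11.5 to E15.5. Called below were 2, 4 and 3 in the same order. The entries Col6a3, Ahsp, Piezo1 and Piezo2 matched no symbol under those names and were not analysed here.

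Genes were named by a rule fixed before the data were examined: in each comparison the 10 largest increases and 10 largest decreases among genes with status OK and at least 10 FPKM in the higher library, up to 4 members of each list with the largest change in the comparison described, up to 10 genes highest or lowest at E13.5, and at any size of change Scx, Mkx, Egr1, Tnmd, Col1a1, Col1a2, Fmod, Sox9, Col2a1, Gdf5, Myod1, Myog, the tendon regulators and the sex-linked genes. Predicted genes, clone names, small nucleolar RNAs and microRNAs were counted but not named. Single values of 2 genes the rule would name are not reported here, though both count in the list medians. The rule also asked for intervals that do not overlap where a table gives them, which was not applied since the tables hold none. Coordinates are those of the deposited mm9 tables, written 1-based.

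The calls were tested on simulated libraries with 10928 genes and counting noise only. Noise from amplification and differences between pools were not simulated, so the rates do not describe calls in the real libraries. A planted 4-fold change was called in 84% of 100 genes for E11.5 to E13.5, 97% for E13.5 to E15.5 and 84% for E11.5 to E15.5, and in 100% of those at 5 FPKM or more. A planted 2.83-fold change was called in 78%, 74% and 78% of 100 genes in the same order. Unshifted lists were called apart in 4.5%, 6.5% and 4% of 200 draws. They were drawn at random like the lists they were set against, so these rates check the computation only. The alternatives tried were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, rescaling of each library to a sum of 1000000, median-of-ratios size factors (0.976, 1.01 and 1.02), rescaling without erythroid and muscle genes, a 4-fold threshold, genes of every status, and transcript rows as deposited. Rescaling multiplies every FPKM by more than 5, so the pseudocount also weighs less there. Rescaling without Lars2 and Mtrnr2l, the most abundant genes, rescaling to the mean of the 3 sums, which keeps that weight, and leaving out genes under 300 bases were added after seeing the data. List medians under each alternative were first compared by the size of their move. After those values were seen, the comparison was changed to whether the median kept its place against random lists drawn from the same values. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.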

Results

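Gene expression was measured by RNA sequencing in ScxGFP-positive cells of the mouse embryonic hindlimb. Scx encodes scleraxis, a transcription factor of tendon and ligament progenitors, and the GFP reporter marks cells in which it is active. GFP-positive cells were sorted by flow cytometry from 18 pooled hindlimbs at E11.5, 12 at E13.5 and 11 at E15.5, and each pool gave 1 library. With 1 library per stage, no difference between stages has a replicate check, so no p-value is given and each difference is one between 2 libraries. The tables list 22072 gene symbols. Of these, 10364 reached at least 1 FPKM at E11.5, 10971 at E13.5 and 11132 at E15.5. Depth estimated from the coverage was about 14400000, 12800000 and 17900000 reads in stage order. A transcript of 2000 bases at 1 FPKM was then covered by about 78.7, 64.5 and 77.1 reads, a counting error of 11.3%, 12.5% and 11.4%. Intervals given for single genes are approximate 95% Poisson intervals that cover counting error only. Across 10928 genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.921 between E11.5 and E13.5, 0.944 between E13.5 and E15.5 and 0.827 between E11.5 and E15.5.

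Scx itself, the gene behind the sort, was abundant in every library and is given first as a check of the labels, not as a finding between stages. Its transcript NM_198885 (mm9, chromosome 15, 76287868 to 76289898) stood at 375 FPKM at E11.5 (interval 369 to 380), 410 at E13.5 (403 to 416) and 213 at E15.5 (209 to 217). Of the genes that take part in tendon formation with Scx, Mkx, which encodes the homeobox factor Mohawk (NM_177595, chromosome 18, 6934964 to 7004777), was at 1.44, 15.1 and 13.2 FPKM. Egr1, an immediate-early transcription factor also known to act in tendon cells (NM_007913, chromosome 18, 35020861 to 35024610), was at 13.8, 87.5 and 298 FPKM. Tnmd, which encodes the tendon membrane protein tenomodulin (NM_022322, chromosome X, 130385547 to 130400116), was listed at 0 at E11.5 and reached 7.57 FPKM at E13.5 (6.76 to 8.43) and 56.8 at E15.5 (54.8 to 58.9).

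**Figure D1:**
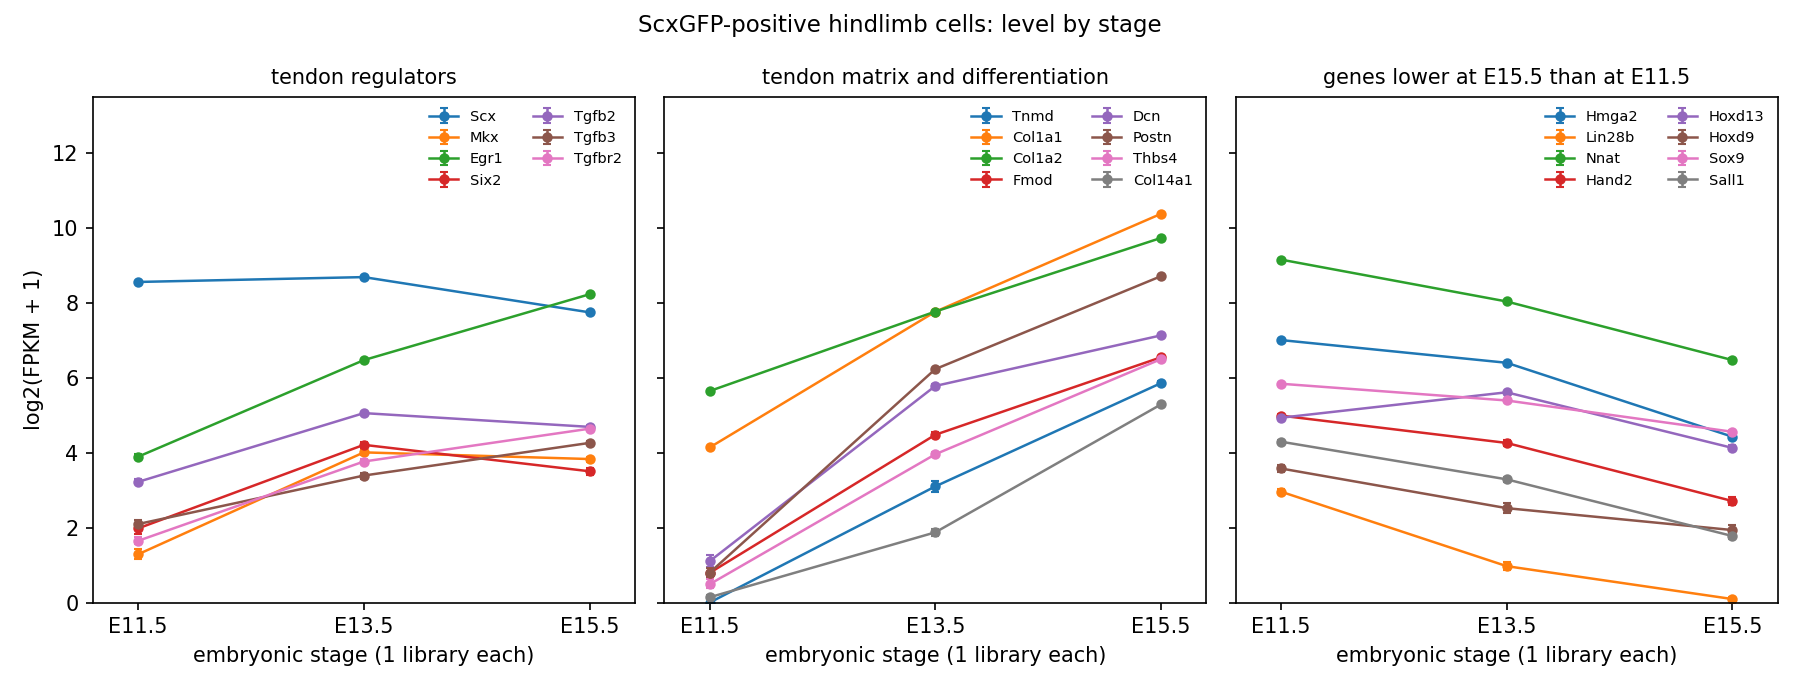
Level of 23 genes, as log2(FPKM + 1) on the vertical axis, at each embryonic stage on the horizontal axis; each point is 1 library and bars are approximate 95% counting intervals, not replicate error. Scx stays between 213 and 410 FPKM, the matrix genes climb to between 38.0 FPKM (Col14a1) and 1322 FPKM (Col1a1) at E15.5, and the genes in the right panel are lower at E15.5 than at E11.5.

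The comparison of E13.5 with E11.5 asks how expression in the sorted population differed across the earlier step. Genes of the tendon matrix were higher at E13.5: all 21 measured members of that list were at least 2-fold higher, with a median log2 change of 3.03 (bootstrap interval 2.27 to 3.30) against -0.19 to 0.25 for the middle 95% of random lists. Postn, which encodes the matrix protein periostin, went from 0.737 to 73.9 FPKM, the collagen-binding proteoglycan gene Dcn from 1.15 to 53.9, and Fmod, which encodes the proteoglycan fibromodulin, from 0.730 to 21.3. Genes of limb bud patterning and of the cell cycle had lower medians, at -0.36 and -0.54. In all, 656 of 10938 compared genes were at least 2-fold higher at E13.5 and 112 were at least 2-fold lower. With a pseudocount of 0.1 these counts were 1154 and 191, rescaled to a sum of 1000000 they were 1162 and 164, and with a mean of at least 5 FPKM 381 and 43.

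Collagens and the enzymes that process them were higher together. All 13 measured fibrillar and fibril-associated collagens were at least 2-fold higher (median 2.24, 1.72 to 2.57), among them Col1a1, the main chain of type I collagen (16.6 to 215 FPKM), Col6a1 (1.49 to 25.7) and Col6a2 (3.23 to 41.7). Of 25 measured genes of collagen processing and crosslinking, 14 were at least 2-fold higher and none lower (median 1.10), with Sparc, which encodes osteonectin, at 15.8 and 159 FPKM and the crosslinking enzyme Lox at 0.669 and 12.1. For the elastic fibre and microfibril list, 8 of 17 members were higher and none lower (median 0.98), including elastin, Eln, at 1.32 and 11.1 FPKM. Among matrix proteases and their inhibitors 11 of 18 were higher and none lower (median 1.08), led by Adamts9 at 0.909 and 9.09 FPKM. These medians were above those of all 10000 random lists matched on expression.

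Tendon regulators were higher at E13.5 as a list, with 8 of 15 members at least 2-fold higher, none lower and a median of 1.29 (0.45 to 2.12). Besides Mkx and Egr1, the homeobox gene Six2 was at 2.94 and 17.5 FPKM, the TGF-beta receptor gene Tgfbr2 at 2.13 and 12.6, its ligand gene Tgfb2 at 8.32 and 32.2, and Tgfb3 at 3.27 and 9.47. Eya1 was at 1.88 and 4.27 FPKM, Eya2 at 1.86 and 4.03, Foxp1 at 5.50 and 22.0, Smad3 at 8.67 and 13.8, Tcf7l2 at 49.9 and 44.5, and Tgfbr1 at 17.7 and 16.3. Egr2 was at 0.328 and 2.42 FPKM, Tgfb1 at 0.0271 and 0.541 and Gdf7 at 0.264 and 0.481. Of 29 TGF-beta and BMP pathway genes, 10 were higher and 1 lower (median 0.64), with the ligand genes Gdf10 at 0.796 and 12.3 FPKM and Inhba at 0.420 and 6.77.

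Cartilage genes were also higher at E13.5, with 14 of 20 members at least 2-fold higher and none lower (median 1.76, 0.90 to 2.4996). Matn1, which encodes the cartilage protein matrilin-1, was at 0.0635 and 6.38 FPKM and the link protein gene Hapln1 at 0.237 and 8.61. Sox9, the transcription factor of cartilage progenitors, was at 56.2 and 41.0 FPKM, and the type II collagen gene Col2a1 at 67.3 and 138. In the hypertrophic cartilage and bone list, 5 of 8 measured members were higher (median 1.45), including the osteoblast factor Runx2 at 3.71 and 13.4 FPKM. In the joint and ligament list, 6 of 10 were higher (median 1.10), including the ETS factor gene Erg at 0.708 and 7.65 FPKM, while the joint marker Gdf5 was at 2.70 and 5.03.

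On the lower side, 8 of 28 limb bud patterning genes were at least 2-fold lower at E13.5 and 2 were higher (median -0.36, -0.94 to 0.16). Lin28b, which encodes an RNA-binding protein of early embryonic cells, was at 6.77 and 0.962 FPKM, Sall3 at 3.05 and 0.251, and the BMP antagonist gene Grem1 at 9.45 and 2.48, whereas Tbx5 was at 0.251 and 2.66. The median of the patterning list stood at -0.07, inside the random range, when members had to average at least 5 FPKM. Of 34 cell cycle genes, 3 were above their E11.5 level and 1 was at least 2-fold lower (median -0.54, -0.64 to -0.40): Rrm2, a subunit of ribonucleotide reductase, at 42.6 and 16.0 FPKM. The largest decreases among named genes with at least 10 FPKM in the higher library were those of Hsd11b2 (19.98 and 1.44 FPKM), Lix1 (14.7 and 2.40), Fndc3c1 (32.1 and 7.16), the chromatin protein gene Hmga1 (185 and 49.0), Asb4 (81.4 and 24.0), the Wnt antagonist gene Frzb (12.0 and 3.11), Car14 (11.3 and 3.03), Chd7 (12.5 and 3.61), the retinoic acid-degrading enzyme gene Cyp26b1 (23.9 and 7.72) and Meis2 (16.1 and 5.04). Other large increases under the same limit were those of Egfl6 (0.728 and 40.8), Cthrc1 (3.15 and 52.6), the enkephalin precursor gene Penk (1.24 and 27.2), Cytl1 (0.451 and 15.9) and Thbs4 (0.403 and 14.5).

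Further lists with medians above the random range at this step included immediate-early and dissociation stress (10 of 21 higher, median 0.86), imprinted growth genes (4 of 12, 0.45), integrins and mechanosensing (2 of 17, 0.56), dermal and connective fibroblast (3 of 9, 0.48) and the retinoic acid pathway (2 of 12 higher and 1 lower, 0.41, but 0.04 and within random lists among members that averaged at least 5 FPKM). Among their members, the immediate-early gene Fosb was at 1.85 and 19.2 FPKM, the imprinted gene Dlk1 at 7.61 and 44.3, the collagen-binding integrin gene Itga11 at 1.74 and 7.41, and Crabp1 at 79.1 and 178. The FGF pathway (median 0.29, but 0.49 and above random lists with a pseudocount of 0.1, and likewise in 3 rescaled alternatives), the Wnt pathway (0.05), cell cycle inhibitors (0.33), glycolysis and hypoxia (0.03), ribosomal proteins (-0.28, below random lists without the filter on low values), housekeeping genes (-0.16) and the HoxA and HoxD genes 9 to 13 (-0.04) lay within the range of random lists. Differentiated skeletal muscle genes were higher at the same step, in 9 of 17 members (median 1.0006), with the cardiac actin gene Actc1 at 5.35 and 39.3 FPKM, so muscle transcripts moved with the matrix lists.

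The comparison of E15.5 with E13.5 covers the later step. Matrix genes were higher again at E15.5: 16 of 21 tendon matrix genes were at least 2-fold higher and none lower (median 1.96, 1.45 to 2.498), and so were 10 of 13 fibrillar and fibril-associated collagens (median 1.84, 1.43 to 2.19). Col1a1 went from 215 to 1322 FPKM, Col14a1, a fibril-associated collagen gene, from 2.66 to 38.0, the proteoglycan gene Bgn from 27.1 to 187, and Thbs2 from 7.46 to 53.3. The HoxA and HoxD genes 9 to 13, which pattern the limb along its length, were lower, in 6 of 9 members (median -1.14, -1.31 to -0.73). As deposited, 391 of 10934 compared genes were at least 2-fold higher and 78 lower, so 83.4% of the genes past the threshold were higher.

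That split moved with the scaling and with the pseudocount. With size factors, 382 genes were higher and 80 lower (82.7% higher). With each library rescaled to the mean of the 3 sums, an alternative added after seeing the data, they were 288 and 139 (67.4%), and the median change of all genes was -0.13 instead of 0.04. A pseudocount of 0.1 alone gave 584 and 189 (75.5%). Rescaling to a sum of 1000000, which changes the scaling and the weight of the pseudocount together, gave 405 and 299 (57.5%). List medians are set against random lists taken from the same values, which carry the same shift.

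As a list, tendon regulators did not share the second increase. Their median was -0.14 (-0.36 to 0.845), just below the range of random lists (-0.13 to 0.26), and inside it without the filter on low values. The list includes Scx, the gene behind the sort, at 410 and 213 FPKM, so a median this close to the range is not read as a decrease. Of 15 members, 1 was at least 2-fold higher and none lower. That member was Egr1 (87.5 to 298 FPKM). Mkx was at 15.1 and 13.2 FPKM, Six2 at 17.5 and 10.3, Tgfb2 at 32.2 and 24.8, Tgfb3 at 9.47 and 18.2, and Tgfbr2 at 12.6 and 23.9. Eya1 was at 4.27 and 3.12 FPKM, Eya2 at 4.03 and 5.54, Smad3 at 13.8 and 11.6, Foxp1 at 22.0 and 19.8, Tcf7l2 at 44.5 and 41.1, Tgfbr1 at 16.3 and 13.1, Egr2 at 2.42 and 5.15, Tgfb1 at 0.541 and 1.27 and Gdf7 at 0.481 and 1.32. The TGF-beta and BMP list had a median of 0.04, within the random range. Inside it Id1 and Id2, targets of BMP signalling, were lower, at 92.6 and 33.8 FPKM and at 22.6 and 7.73, while Inhba was at 6.77 and 21.8.

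Collagen processing and crosslinking genes were higher in 9 of 25 members and lower in none (median 0.89), with Lox at 12.1 and 54.6 FPKM and the procollagen protease enhancer gene Pcolce at 29.5 and 100.2. Elastic fibre and microfibril genes were higher in 9 of 17 (median 1.12), with Eln at 11.1 and 51.8 FPKM and Mfap5 at 0.615 and 13.4. In the cartilage list 6 of 20 were at least 2-fold higher and none lower, and 14 of 20 were above their E13.5 level. The median was 0.71, with a bootstrap interval of -0.10 to 1.01 that includes no change. The proteoglycan gene Acan was at 4.73 and 17.9 FPKM, Col2a1 at 138 and 230, and Sox9 at 41.0 and 22.5. Matrix proteases and inhibitors were higher in 5 of 17 members (median 0.84), with Adam12 at 5.20 and 15.8 FPKM. Hypertrophic cartilage and bone genes (median 0.09, but -0.42 and below random lists among members that averaged at least 5 FPKM) and joint and ligament genes (0.24) lay within the random range. Among those, Runx2 was at 13.4 and 6.60 FPKM, Gdf5 at 5.03 and 2.04, and the hyaluronan receptor gene Cd44 at 2.995 and 22.7.

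Besides the Hox genes, limb bud patterning genes were lower as a list (median -0.43, -0.54 to -0.17), with 2 of 28 members at least 2-fold lower, Hand2 (18.1 and 5.54 FPKM) and Sall1 (8.76 and 2.42). Among the Hox genes Hoxd13 was at 47.8 and 16.5 FPKM, Hoxd11 at 9.12 and 3.08, and Hoxa13 at 16.2 and 6.005. Among named genes with at least 10 FPKM in the higher library, the largest decrease was that of Hmga2, which encodes a chromatin protein of embryonic cells (83.3 and 20.5 FPKM), followed by Hey1 (18.7 and 4.05), Sox11 (45.9 and 13.498), the imprinted gene Nnat (261 and 87.6), Hand2, Hoxd13, Id2, Id1, Fblim1 (20.1 and 6.99) and the surface protein gene Cd24a (165 and 62.1). The largest increases under the same limit were those of Nov (0.258 and 16.0 FPKM), Fndc1 (1.53 and 32.2), the beta-globin gene Beta-s (4.93 and 67.4), Col14a1, Mfap5, the Wnt antagonist gene Sfrp4 (0.343 and 10.9), C1qtnf3 (1.51 and 19.96), the dermatopontin gene Dpt (0.4002 and 10.4), Cck (0.820 and 13.03) and the secreted protease gene Htra1 (6.07 and 52.1).

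Imprinted growth genes were higher in 4 of 12 members (median 0.95), with Dlk1 at 44.3 and 245 FPKM and the zinc finger gene Plagl1 at 34.1 and 201. Glycolysis and hypoxia genes had a median of 0.54, with 2 of 18 at least 2-fold higher, Ndrg1 (1.48 and 6.48 FPKM) and Egln3 (1.34 and 3.90). The FGF pathway (4 of 17 higher, median 0.44), integrins and mechanosensing (2 of 17, 0.41), immediate-early and dissociation stress (6 of 21, 0.78) and cell cycle inhibitors (0 of 8, 0.49) were also above random lists. Their examples include Fgf2 at 2.98 and 8.22 FPKM, Ctgf at 6.26 and 15.01, Zfp36 at 8.77 and 32.1, and the cyclin-dependent kinase inhibitor gene Cdkn1c at 165 and 324. Cell cycle genes (-0.01), the Wnt pathway (-0.05), the retinoic acid pathway (0.18), dermal and connective fibroblast genes (0.05, but 0.35 and above random lists without the filter on low values), ribosomal proteins (0.22) and housekeeping genes (0.20) lay within the random range. Differentiated muscle genes were higher at this step too, in 8 of 17 members (median 0.99) and the muscle progenitor list in 3 of 5 (median 1.17).

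**Figure D2:**
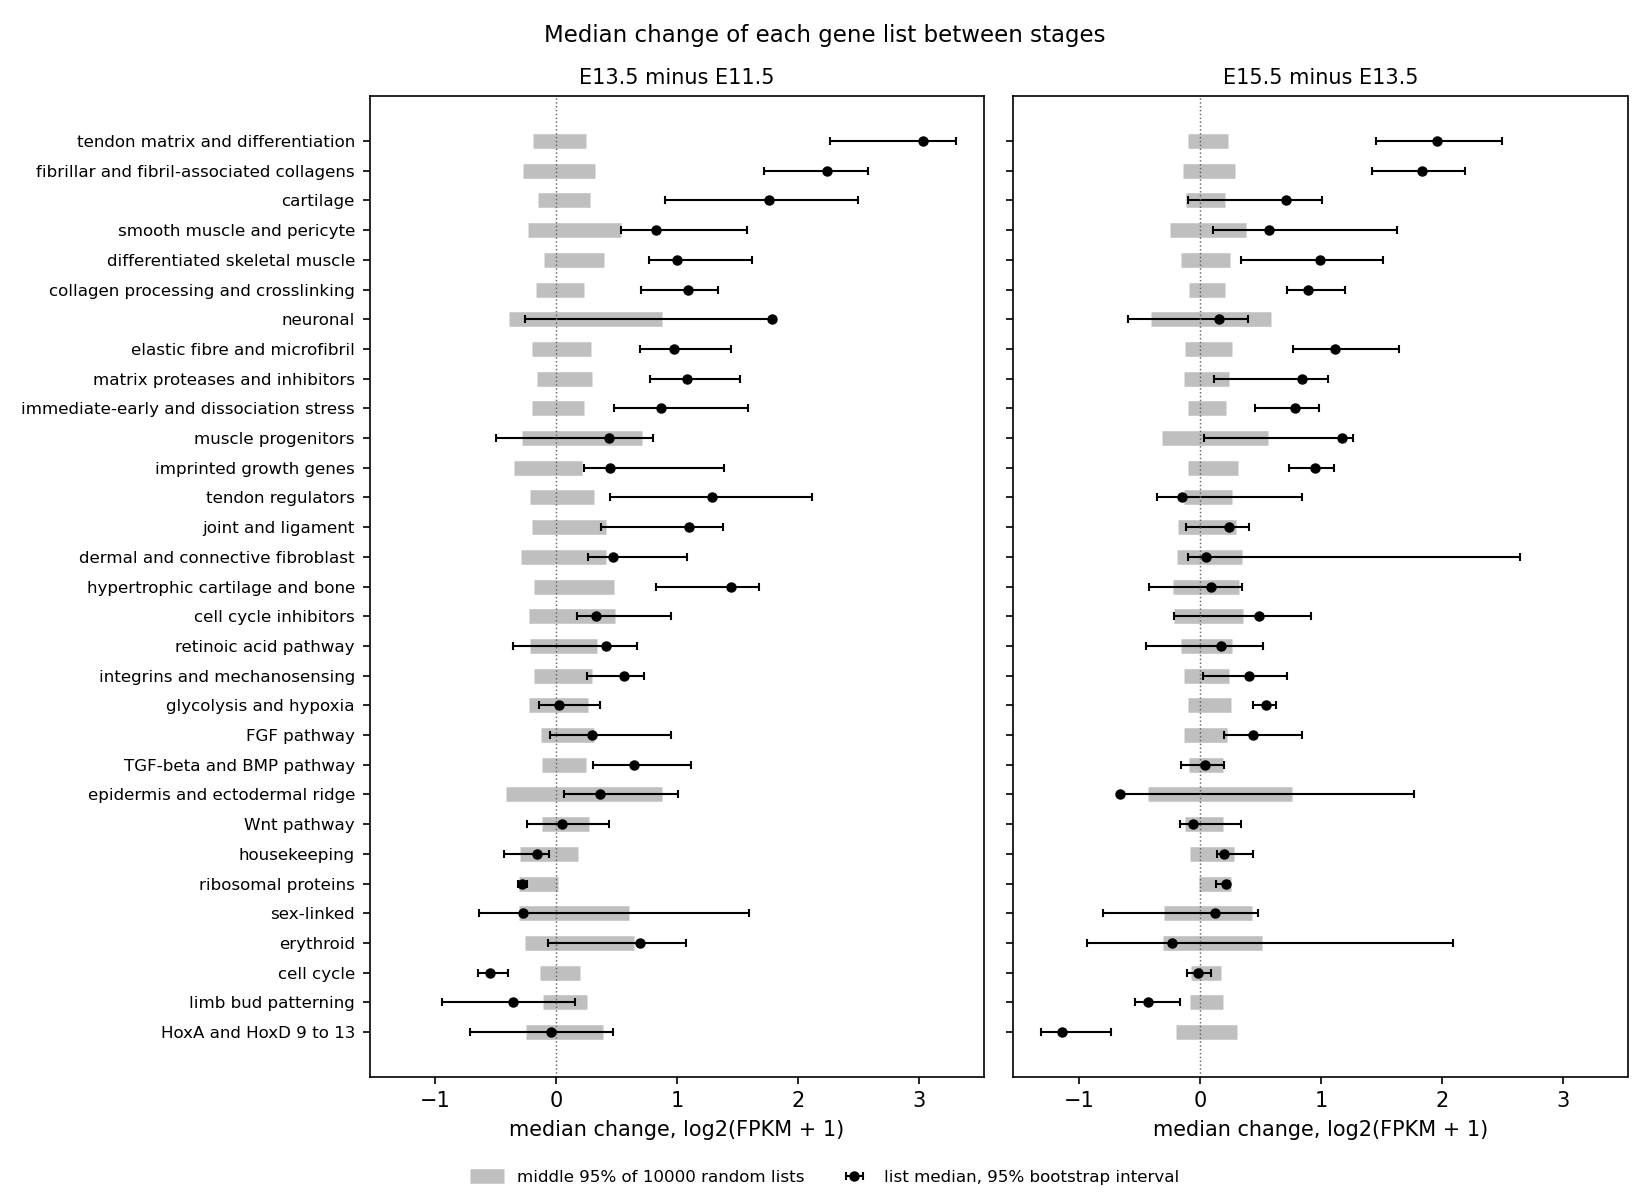
Median change of each compared gene list on the horizontal axis, in units of log2(FPKM + 1), with 1 row per list, for E13.5 minus E11.5 (left) and E15.5 minus E13.5 (right). Black points are medians with 95% bootstrap intervals over members and grey bars the middle 95% of 10000 expression-matched random lists; tendon matrix stands at 3.03 and 1.96, and tendon regulators at 1.29 and -0.14.

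The comparison of E15.5 with E11.5 spans both steps. Among named genes with at least 10 FPKM in the higher library, the largest increases included those of matrix genes: Postn from 0.737 to 417 FPKM, Col1a1 from 16.6 to 1322, Dcn from 1.15 to 139, Thbs4 from 0.403 to 89.1, Col6a1 from 1.49 to 144, Fmod from 0.730 to 92.2, Htra1 from 0.110 to 52.1 and Col6a2 from 3.23 to 194. Tnmd, listed at 0 at E11.5, and Beta-s (0.308 to 67.4) were the others among the first 10. The largest decreases under the same limit were those of Hsd11b2 (19.98 to 0.570 FPKM), Lix1 (14.7 to 1.196), Nnat (567 to 87.6), Car14 (11.3 to 0.928), Cd24a (393 to 62.1), Hmga2 (127 to 20.5), Sall1 (18.6 to 2.42), Mecom (62.0 to 10.02), Fndc3c1 (32.1 to 5.63) and Hand2 (30.7 to 5.54). In all, 1380 of 10939 compared genes were at least 2-fold higher at E15.5 and 234 lower, or 85.5% higher among those past the threshold; with each library rescaled to the mean of the 3 sums the counts were 1174 and 361, or 76.48%, rescaled to a sum of 1000000 they were 1514 and 619, or 70.98%, and rescaled without Lars2 and Mtrnr2l 1496 and 658, or 69.45%.

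All 21 measured tendon matrix genes were at least 2-fold higher at E15.5 than at E11.5 (median 4.82, 4.08 to 5.46), as were all 13 collagens of the fibrillar list (4.08), 23 of 25 genes of collagen processing (1.98), 16 of 17 elastic fibre and microfibril genes (1.92) and 14 of 17 matrix proteases and inhibitors (1.88). Col1a2, the partner chain of Col1a1, was at 49.0 FPKM at E11.5, 216 at E13.5 and 846 at E15.5. Tendon regulators were higher in 9 of 15 members and lower in none (median 1.47). Cartilage genes were higher in 15 of 20 (median 2.64) and lower in 1, Sox9, at 56.2 and 22.5 FPKM. Hypertrophic cartilage and bone genes (4 of 8 higher, median 1.02) and joint and ligament genes (6 of 10, 1.29) were above random lists, the former inside the random range when members had to average at least 5 FPKM.

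Limb bud patterning genes were lower in 11 of 28 members and higher in 1 (median -0.79, -1.19 to -0.29). HoxA and HoxD genes 9 to 13 were lower in 5 of 9 (median -1.01, -1.44 to -0.83), with Hoxd9 at 10.9 and 2.82 FPKM. Cell cycle genes were lower as a list (median -0.51, -0.65 to -0.37), with 3 of 34 at least 2-fold lower: Bub1 (14.2 and 6.05 FPKM), Rrm2 (42.6 and 20.1) and Aurka (12.7 and 5.78). Cell cycle inhibitors were higher in 3 of 8 (median 0.86), among them Cdkn1c at 91.35 and 324 FPKM. Imprinted growth genes were higher in 8 of 12 (median 1.497), with Plagl1 at 6.30 and 201. Immediate-early and dissociation stress genes were higher in 15 of 21 (median 1.83), glycolysis and hypoxia genes in 3 of 18 (0.59), integrins and mechanosensing in 4 of 17 (0.79), FGF pathway genes in 8 of 17 (0.51) and TGF-beta and BMP pathway genes in 10 of 29 (0.38). The FGF and the TGF-beta and BMP medians lay within random lists among members that averaged at least 5 FPKM (0.46 and 0.35).

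Retinoic acid pathway genes went both ways, with 4 of 12 higher and 3 lower. Their median of 0.79 turned to -0.46 among members that averaged at least 5 FPKM. The synthetic enzyme gene Aldh1a3 was at 0.0231 and 4.82 FPKM, and the retinol uptake receptor gene Stra6 at 12.3 and 2.76. The Wnt pathway (0.19), ribosomal proteins (-0.05) and housekeeping genes (0.10) lay within the random range. Sex-linked genes did too (-0.15). Xist, expressed from the inactive X of females, was at 15.49, 48.8 and 27.7 FPKM in stage order. The Y-linked Ddx3y was at 3.14, 2.75 and 4.23, Eif2s3y at 9.73, 6.57 and 7.59, Kdm5d at 4.28, 2.40 and 2.57 and Uty at 2.18, 1.63 and 1.86. X-inactivation and Y-linked transcripts were thus both present in every library. At E13.5 Xist was higher than at E11.5 and each of these Y-linked genes lower, and the later step went the other way. A median over both kinds cannot show such opposite changes. The mix of males and females in the pools was not measured, so a difference in it between stages is not excluded.

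Of the 10928 genes compared in all 3 libraries, 178 were at least 2-fold higher at both steps and 10 lower at both, and 16 were at least 2-fold highest and 11 at least 2-fold lowest at E13.5. The 2 steps share the E13.5 library, so a count expected from independent steps is not a chance level, and none is given. The numbers highest and lowest at E13.5 moved to 45 and 74 by transcript row, to 43 and 17 rescaled to a sum of 1000000, to 6 and 1 with a mean of at least 5 FPKM, and to 9 and 4 without genes under 300 bases. Of the named genes with at least 10 FPKM, Id2 (8.67, 22.6 and 7.73 FPKM) and the kinase gene Plk2 (8.33, 20.5 and 9.60) were highest at E13.5.

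Markers of other cell types were followed as a check on what the sort held. At E15.5, 15 of 17 differentiated muscle genes were at least 2-fold above E11.5 (median 2.18), with Actc1 at 164 FPKM, the troponin gene Tnnt1 at 32.5, the fusion factor gene Tmem8c at 14.1 and the myogenic factor Myog at 12.2 (0.880 at E11.5). Myod1, which sets muscle identity, was at 0.906, 1.96 and 6.11 FPKM. The muscle progenitor list was above random lists over both steps together, with 3 of 5 members at least 2-fold higher (median 1.70). The bootstrap interval of that median, -0.46 to 1.97, includes no change, and the median was 0.05 without the filter on low values. Erythroid genes split: some adult globin genes were higher at E15.5 (Hbb-b1, listed at 0 at E11.5, 7.97 FPKM; Hba-a1, 0.175 and 5.71; Beta-s, 0.308 and 67.4), while the embryonic globin genes Hbb-y (4.20 and 3.41) and Hba-x (4.39 and 2.88) were not. The erythroid median was 0.70 at the first step, -0.23 at the second and -0.24 over both.

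Endothelial genes were low, with Emcn at 0.0174, 0.540 and 2.87 FPKM and Tek at 0.151, 0.686 and 2.63. These 2 were the only measured members and were too few to be set against random lists. Both passed the filter on the mean only through their E15.5 level. Their median (1.79 over both steps) follows in part from that filter and is not read as a change of the list. The macrophage and leukocyte list had 1 measured member, Cd68, at 1.65, 0.652 and 0.909 FPKM. In the Schwann and neural crest list, Ngfr, also expressed outside glia, was at 1.62, 7.06 and 26.0 FPKM. Neuronal genes had 3 measured members (median 1.94 over both steps, but 0.055 and within random lists without the filter on low values), with Nefl at 0.168, 3.04 and 4.32 FPKM and Isl1 at 3.17, 2.498 and 1.32. Among 3 epidermal genes (median 0.35 over both steps and -0.66 at the later one, below random lists, but 0.35 and above them at the later step without the filter on low values), Krt5 was at 0.0525, 0.352 and 3.60 FPKM and Krt18 at 2.54, 2.71 and 1.36. Smooth muscle and pericyte genes were higher at E15.5 in 6 of 7 members (median 2.19), with Acta2 at 2.205, 12.1 and 18.5 FPKM. Dermal and connective fibroblast genes were higher in 5 of 9 (median 1.09, but 0.84 and within random lists among members that averaged at least 5 FPKM), with Cd34 at 0.155, 1.37 and 13.9 FPKM.

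**Figure D3:**
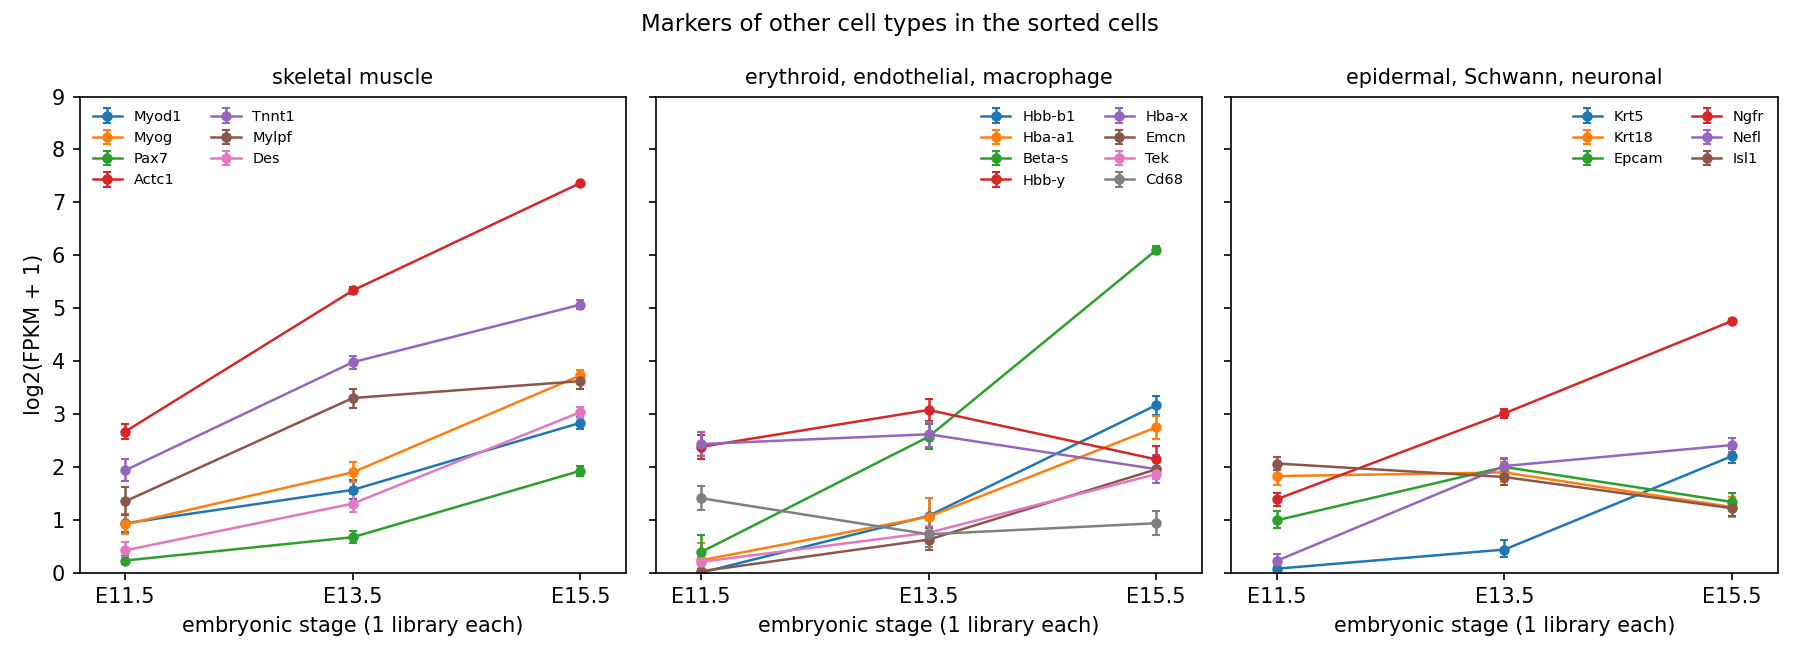
Level of 21 marker genes of other cell types, as log2(FPKM + 1) on the vertical axis, at each embryonic stage on the horizontal axis; each point is 1 library and bars are approximate 95% counting intervals, not replicate error. Actc1 reaches 164 FPKM and Beta-s 67.4 at E15.5, while Cd68 stays below 2 FPKM in every library.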

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

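Genes outside the comparisons for their estimation status were looked at separately, since a signal there is not seen in the report. Of 88 genes with a mean of at least 1 FPKM that were left out of the comparison of E15.5 with E11.5, 16 still differed at least 2-fold in summed FPKM, 11 higher and 5 lower at E15.5. Named products among them, chosen after their values were seen, include the cardiac troponin gene Tnnt2 (0.415, 3.65 and 21.5 FPKM in stage order), the netrin-related gene Ntng1 (1.02, 10.2 and 9.09) and Sept2 (18.8, 36.1 and 47.6). Asph was at 18.5 FPKM at E11.5 and listed at 0 at both later stages, where each of its 10 transcripts had a failed status, so a failed estimate and a low level were not separated. With genes of every status counted, 1391 were higher and 239 lower at E15.5 than at E11.5, against 1380 and 234.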

How the results depend on the processing

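Alternatives that leave out Lars2 and Mtrnr2l or genes under 300 bases or that rescale to the mean of the 3 sums, and the rule that places list medians against random lists, were chosen after seeing the data. No paired analysis was possible because each stage has 1 library and no test was made; leaving out a replicate was not possible for the same reason. The count with intervals per gene that do not overlap was not run, since the tables used here hold none. Depth limits low genes most: at 1 FPKM the counting error of a transcript of 2000 bases was 11.3% to 12.5%. With size factors and with genes of every status the 8 counts were within 1.5 times the main counts; of 96 counts under alternatives, 49 were not. More genes were higher than lower in every comparison under every setting tried. Causes were not tested beyond what a setting does by construction (a stricter threshold or filter leaves fewer genes).

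With a pseudocount of 0.1, 1154 genes were higher and 191 lower at E13.5 than at E11.5, 189 lower at E15.5 than at E13.5, 431 lower at E15.5 than at E11.5, 34 highest and 21 lowest at E13.5. With no filter, 28 were highest at E13.5. With a mean of at least 5 FPKM, the counts were 381 higher and 43 lower, 214 and 42, and 712 and 124 in the same order of comparisons, with 6 highest and 1 lowest at E13.5. At a 4-fold threshold they were 132 and 10, 64 and 10, and 398 and 34, with 3 and 0. Rescaled to a sum of 1000000, which also lowers the weight of the pseudocount, 1162 were higher at E13.5 than at E11.5, 299 lower at E15.5 than at E13.5, 619 lower at E15.5 than at E11.5, 43 highest and 17 lowest at E13.5. Without erythroid and muscle genes the same counts were 1144, 297, 615, 43 and 17. Without Lars2 and Mtrnr2l they were 1147, 303, 658, 42 and 17, with 172 lower at E13.5 than at E11.5. Rescaled to the mean of the 3 sums, which leaves that weight unchanged, 139 were lower at E15.5 than at E13.5, 361 lower at E15.5 than at E11.5 and 26 highest at E13.5. By transcript row, 247, 190 and 356 were lower in the order of comparisons, 45 highest and 74 lowest at E13.5. Without genes under 300 bases 9 were highest and 4 lowest at E13.5. The median change of all genes moved from 0.07, 0.04 and 0.07 to 0.12, -0.15 and -0.07 at a sum of 1000000 and to 0.10, -0.13 and -0.06 at the mean sum.

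Of 717 list medians under alternatives, 688 kept their direction and their place against random lists, 15 lost it, 12 gained it and 2 reversed; the cause was not tested. The reversals were epidermis and ectodermal ridge, E15.5 minus E13.5, at 0.35 with no filter, and the retinoic acid pathway, E15.5 minus E11.5, at -0.46 with a mean of at least 5. With no filter, the place was lost by tendon regulators, E15.5 minus E13.5 (-0.11), muscle progenitors, E15.5 minus E11.5 (0.0491), erythroid, E13.5 minus E11.5 (0), and neuronal, E13.5 minus E11.5 (0.0292) and E15.5 minus E11.5 (0.055). It was gained by epidermis, E15.5 minus E11.5 (0.39), dermal and connective fibroblast, E15.5 minus E13.5 (0.35), and ribosomal proteins, E13.5 minus E11.5 (-0.28). With a mean of at least 5, it was lost by limb bud patterning, E13.5 minus E11.5 (-0.0703), retinoic acid, E13.5 minus E11.5 (0.044), smooth muscle and pericyte, E15.5 minus E13.5 (0.58), and, for E15.5 minus E11.5, hypertrophic cartilage and bone (0.69), dermal and connective fibroblast (0.84), TGF-beta and BMP (0.35) and FGF (0.46). Hypertrophic cartilage and bone, E15.5 minus E13.5, moved below random lists there (-0.42). For E13.5 minus E11.5, erythroid lost its place with a pseudocount of 0.1 (0.81), rescaled (0.84) and without Lars2 and Mtrnr2l (0.82). FGF gained one with a pseudocount of 0.1 (0.49), rescaled (0.51), without erythroid and muscle genes (0.51) and without Lars2 and Mtrnr2l (0.50), and sex-linked likewise (-0.40, -0.35, -0.35 and -0.37). Of 1823 changes of named genes under alternatives, 899 moved by more than their counting interval and 0 of those past 2-fold changed sign.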

Other observations

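The tests on scaling and on Egr1, with its heat-shock test by step, were chosen only after the result was seen; those on low genes and on let-7 targets were written before their values were looked at. The test on scaling was also changed after its values were seen. It first used size factors alone (82.46%), then the lowest of 3 scalings with a sum of 1000000 among them (70.98%), and now the lowest of 3 with the mean of the 3 sums in its place, since the larger sum also changes the weight of the pseudocount. That a share must lie past a bound by its whole binomial interval was added last, after the value of 76.48% was seen. Without that rule the value would have counted against scaling.

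Single members of lists outside tendon are given here as examples with large changes, not as evidence on their lists; the Wnt pathway list lay within random lists in all 3 comparisons. Dkk3 was at 1.403, 9.85 and 27.9 FPKM in stage order, Dkk2 at 0.841, 12.9 and 17.3, and Sfrp2 at 39.6, 104 and 134, while Frzb was at 12.0, 3.11 and 2.60. The growth factor gene Fgf7 was at 0.849, 2.96 and 8.475 FPKM, the receptor gene Fgfr4 at 0.923, 1.67 and 7.30, and the feedback gene Spry4 at 2.43, 7.78 and 16.6, with Dusp6, another feedback gene, at 18.98, 7.83 and 6.24. Of the imprinted genes, Meg3 was at 27.5, 85.5 and 144 FPKM, Igf2r at 15.2, 35.5 and 67.6, and Peg3 at 128, 130 and 276. Lars2 and Mtrnr2l together held 3.42%, 2.31% and 2.23% of the summed FPKM.

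More genes were higher than lower from E11.5 to E15.5, 1380 against 234. The imbalance was not confined to genes low in all 3 libraries, though most of the genes counted averaged below 10 FPKM. Among genes with a mean of at least 10 FPKM 421 were higher and 69 lower, a share of 85.92% (binomial interval 82.6% to 88.7%). A gene near the floor in 1 library can pass this filter on the mean, as did Postn at 0.737 FPKM at E11.5 and 417 at E15.5. The test therefore cannot exclude genes near the floor at 1 stage. Scaling stays open as part of the cause. Over the values as deposited, size factors and rescaling to the mean of the 3 sums, the lowest share of higher genes was 76.48%. Its binomial interval of 74.3% to 78.5% includes the bound of 75% and lies above that of 60%. Both binomial intervals treat genes as independent, which they are not, and cover neither scaling nor differences between libraries. The test therefore does not decide on scaling. At the later step size factors left the share at 82.7% and rescaling to the mean sum took it to 67.4%. A difference between stages in the RNA content of these cells was not tested.

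Egr1 was at 13.8, 87.5 and 298 FPKM. A candidate explanation is a response to tissue dissociation and sorting that grows with the age of the tissue. Of the other 20 measured genes of the immediate-early list, 14 were at least 2-fold higher at E15.5 than at E11.5, 0 were at least 2-fold lower and Hspa8 was slightly lower, with a median of 1.74 at percentile 100 of matched random lists. Heat-shock type stress as a source was set against Hspa8 and the sum of the near-identical copies Hspa1a and Hspa1b. From E11.5 to E13.5 both were lower (-0.60 and -0.63) while Egr1 was higher by 2.58, so these 2 readouts gave no sign of it at that step. With so few genes and 1 library per stage they cannot exclude it. In the immediate-early list, 10 of 21 genes, Egr1 included, were at least 2-fold higher at that step. From E13.5 to E15.5 the changes of Hspa8 and of the sum were 0.37 and 1.64, so heat-shock type stress stays open there too. Growth factor signalling is also known to induce immediate-early genes, and regulation of Egr1 in tendon cells with stage stays untested.

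Skeletal muscle genes were higher with stage although the sort selected for the Scx reporter. The most abundant members of the differentiated muscle list among those compared were Actc1 (164 FPKM at E15.5) and Tnnt1 (32.5), against 1322 for Col1a1. The source of these transcripts was not tested. A test on the spread of their changes was dropped after its value was seen, since its rule could not come out against carried muscle cells and the pseudocount sets part of the spread.

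Lin28b was at 6.77, 0.962 and 0.0673 FPKM and Hmga2, a known target of let-7 microRNAs, at 127, 83.3 and 20.5. Lin28 proteins block the maturation of let-7, so one hypothesis was that other let-7 targets are lower as Lin28b declines. Among 18 measured targets from a list written before their values were looked at, 7 were at least 2-fold lower at E15.5 than at E11.5 and 1 was higher. Their median of -0.66 (bootstrap interval -1.36 to -0.37) was at percentile 0 of random lists, whose middle 95% ran from -0.20 to 0.45. Examples, picked after their values were seen, are Arid3b (8.23 and 0.611 FPKM), Mycn (8.24 and 0.769) and Trim71 (4.71 and 0.0946), while Gatm was at 0.815 and 4.30. The result is consistent with more let-7 activity at E15.5, but several of these targets are also genes of early proliferating cells, and mature let-7 was not measured here.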
